A study of Mus musculus with 2 samples.

How the data were processed

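Single cells of the caudal nucleus of the solitary tract (cNST) of the mouse, a hindbrain region that receives visceral sensory input, were profiled in 2 libraries. The droplet library held cNST tissue pooled from 5 mice, cut as 300 µm sections, dissociated with papain and run on the 10X Chromium system. The plate library came from TRAP2;Ai9 mice, in which cells active during a stimulus express Cre recombinase from the Fos locus and are thereby marked with the red protein tdTomato. Here the stimulus was lipopolysaccharide (LPS), a bacterial wall component that provokes inflammation. Per the labels, 288 tdTomato-positive and 96 tdTomato-negative live cells were sorted into 96-well plates. The number of mice behind the plate library and the treatment of the mice behind the droplet library are not given in the sources used here.

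Both deposited tables held raw counts per gene and cell, in whole numbers. In the droplet table these were counts of unique molecular identifiers (UMIs). Whether the plate table counts molecules or reads is not given in the sources used here. The submitters' processing notes name Cell Ranger and the mouse genome build mm10 for both libraries, without a version. How the plate table was counted, and with which annotation, is not given beyond that. The lowest droplet barcode had 500 UMIs, so no barcode under that total was in the table. The droplet table listed 32285 genes and 8645 barcodes, and the plate one 384 cells and 48531 features. Gene IDs were matched without their version suffix, and 29146 were in both tables. The shared genes held 99.8% of droplet counts and 89.5% of plate counts. The plate cells carried no names that tie them to a gate, so the planned comparison of tdTomato-positive with tdTomato-negative cells was not made, and no gate was inferred from any gene.

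Cells with at least 1000 counts, at least 500 genes and at most 20% mitochondrial counts were used. This left 6251 droplet barcodes, of which Scrublet marked 77 (1.23%) as doublets, and these were removed. No doublet caller was run on the sorted plate cells, of which 336 passed. Droplet counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (seed 0) gave 32 clusters. A cluster took a class from marker genes fixed for 19 classes before the data were examined. It needed at least 3 markers with a UMI in at least 25% of its cells. It stayed unnamed when its 10 leading genes pointed to other classes, or when its median UMI count was below the library median divided by 3 with no marker of its class among its 10 leading genes. Leading genes were ranked by their level over the other cells, with 10 CPM (a gene's count scaled to the total count of the cells) added to both. Pericytes and smooth muscle cells fell into 1 cluster and are given together. Neurons were clustered again alone with the same settings, into 25 clusters. These were grouped by genes with a UMI in at least 50% of the cluster's droplet cells: Chat with Slc18a3 (Chat-rich), otherwise Dbh with Slc17a6 (Dbh-rich), otherwise Slc17a6 without Slc32a1, or Slc32a1 without Slc17a6.

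Each plate cell was given to the droplet cluster whose mean log profile had the highest Spearman correlation with it, over 1868 shared variable genes for classes and 1931 for neuron clusters. The median best correlation was 0.351 for classes and 0.409 for neuron clusters. The step was tested on simulated data: 600 held-out droplet cells were thinned to plate depths, without and with gene-wise factors between the libraries. Neurons went to the correct cluster in 88.7% and 87.0% of cases and to the correct group of clusters in 98.2% and 97.8%. The test used 2000 genes. Slc32a1-rich clusters took 37.5% and 38.0% (true share 37.7%), and Chat-rich ones 6.5% and 6.33% (true share 6.5%). Assignment by nearest droplet neurons, an alternative, gave 38.2% and 6.5% without the factors. With them it gave 43.3% (39.3% to 47.4%) and 3%, so there it drifted towards Slc32a1-rich and away from Chat-rich clusters. With the correlation, classes were correct in 75.8% and 85.5%. True neurons made up 63.8% of the tested cells, and 47.0% and 55.3% of the tested cells were called neurons. Unnamed clusters took 23.7% and 13.7%, though no tested cell came from one. In this simulation the step thus lowered the neuron share. Its depths were drawn from all plate cells, so it does not give the size of such a bias in the plate share.

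The design has 1 library per group and no replicates. No test was made between libraries or between sets of cells, and the cells were not treated as replicates. Shares of cells carry exact Clopper-Pearson 95% intervals, and CPM carry exact Poisson 95% intervals. Ratios of CPM or of shares (folds) carry exact conditional 95% intervals. All of these cover counting error only. For a count of 0 the upper limit is that of 3 counts over the total. Counts were summed over cells, and mitochondrial genes were left out of the total. Plate and droplet levels used the shared genes alone, with totals of 1140860 plate counts and 62407689 droplet counts over neurons. For shares of cells with a count of a gene, each cell was thinned to 2000 counts and shallower cells were left out.

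Dbh-positive neurons were those with at least 2 Dbh UMIs. A gene list member was counted as higher or lower when it had at least 20 counts in the higher group and a fold of at least 2 either way whose interval excluded 1. The median log2 fold of a list was taken over members with at least 10 counts in all and a count in both groups. Members with no count in a group were left out of it, also where they were counted as lower. The median was ranked among those of 10000 random lists of the same size, drawn from 40 bins of expression over genes that met the same rule. This percentile describes a list and is not a test. The genes to be named were fixed by rule: all transmitter and adrenergic genes, up to 5 members each way of each other list by size of fold, and the 10 largest and 10 smallest folds over all genes. Results of 2 list genes are not reported here. The last needed at least 50 counts in the higher group, a count in at least 10% of its cells and an interval excluding 1. For levels by class, a list gene with at least 20 counts in its highest class was named. In simulated counts with known folds, a 2-fold difference was found in the right direction for 98% of genes between the libraries and for 96% between Dbh-positive and other neurons, and a 4-fold difference for 100% of both. The true fold lay in the interval for 94% to 97% of genes. Of 100 simulated lists with no difference, 5 and 4 fell outside the central 95% of random lists, and all 100 raised lists were above it. These simulated counts held counting error alone, and every gene of a raised list was raised 2-fold. They thus do not show how large a difference of a list could be seen between the real libraries.

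The groups, filters, gene lists, markers, the Dbh gate and 26 alternatives were fixed before the data were examined. The grouping of neuron clusters and 3 further alternatives were chosen afterwards. Those fixed beforehand varied the filters, doublets, clustering resolution, class calls from markers per cell, the assignment of plate cells, the thinning, the scaling and the Dbh gate, and weighted droplet neurons to the plate library's cluster makeup. The added ones were a centred correlation, an assignment without transmitter, adrenergic and peptide genes, and a total without 4 genes of ribosomal or repeated sequence. Positions are those of GENCODE vM21 (GRCm38, the assembly of mm10), counted from 1. Of the gene IDs, 48058 plate and 32158 droplet IDs were in that annotation. The work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9.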

Results

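The question here was which cells of the cNST answer to body inflammation. Sorted cells of the LPS library, of both tdTomato gates, were set beside droplet cells of the dissected nucleus. Marked cells could not be told from unmarked ones, so the comparison is not one of marked cells with the nucleus. The droplet table held 84688181 UMIs over 8645 barcodes, and the 6174 cells used had a median of 8834.5 UMIs (1000 to 175197) and 3200 genes. The plate table held 1545272 counts over 384 cells, and the 336 cells used had a median of 4197 counts (1015 to 19444) and 2260.5 genes. Of the droplet barcodes left out, 1464 had under 1000 UMIs and 1074 had over 20% mitochondrial UMIs, with some in both sets. All 48 plate cells left out had under 1000 counts. The long noncoding RNA Gm42418, which overlaps ribosomal RNA repeats, took 3.44% of the droplet counts and 3.95% of the plate counts. There were no replicates, and platform, sorting, mouse line and depth differ between the libraries together with the LPS label.

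Neurons were the largest class among the droplet cells used. They made up 47.9% of droplet cells (95% interval 46.7% to 49.2%, 2960 of 6174). Astrocytes followed with 10.2%, then microglia with 3.34%, oligodendrocytes with 3.11% and their precursors with 2.40%. Ependymal cells, which line the ventricle, made up 1.88%, endothelial cells 1.81%, fibroblasts 1.05%, border macrophages 0.826%, and pericytes with smooth muscle cells 0.599%. A further 26.9% lay in 6 unnamed clusters with a median of 1724 UMIs. By marker genes, 1024 of these 1659 cells were nearest to neurons and 601 to astrocytes. The neuron share was 65.6% of the 4515 cells with a class and depended on the filters and on how classes were called. These are shares of dissociated cells that passed the filters, and not shares of the tissue.

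Among the sorted plate cells, 70.5% were nearest to droplet neurons (65.3% to 75.4%, 237 of 336). Astrocytes made up 7.74% (26 cells), ependymal cells 3.27% (11 cells) and microglia 2.08% (7 cells). There were 5 oligodendrocytes, 4 oligodendrocyte precursors, 4 border macrophages, 2 endothelial cells and 2 fibroblasts. No pericyte or smooth muscle cell was found among 336 cells, which allows a share of up to 0.893%. Unnamed clusters took 38 cells (11.3%). Of the 298 plate cells with a class, 79.5% were neurons (74.5% to 84.0%). These shares are of cells sorted as live and by tdTomato, with cells of both gates in 1 table, and are not shares of the tissue. In the simulation the class step called fewer cells neurons than were true neurons, and the neuron share was higher among deeper plate cells.

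Which neurons were more frequent among the sorted cells than in the droplet library was read from the 25 droplet neuron clusters. Clusters rich in Slc32a1, the vesicular transporter of GABA and glycine, held 63.7% of plate neurons (57.2% to 69.8%, 151 cells). The same 7 clusters held 37.6% of droplet neurons (35.9% to 39.4%, 1114 cells), a ratio of 1.69 (1.42 to 2.01). The 9 clusters rich in Slc17a6, the vesicular glutamate transporter VGLUT2, and not in Dbh showed the opposite order, with 13.9% of plate and 35.9% of droplet neurons, a ratio of 0.388 (0.266 to 0.548). Clusters rich in Dbh, which makes noradrenaline from dopamine, held 22.4% of plate neurons (17.2% to 28.2%, 53 cells) and 18.4% of droplet neurons (17.0% to 19.8%, 544 cells). Their ratio of 1.22 had an interval that included 1 (0.900 to 1.62). The Dbh-rich clusters carry Slc17a6 too, and the 15 clusters of both groups held 36.3% of plate and 54.3% of droplet neurons, a ratio of 0.669 (0.532 to 0.831).

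Of the 6 Dbh-rich clusters, 2 held larger shares of plate than of droplet neurons and 1 a smaller share. Cluster 25, in which all droplet cells had UMIs of Gfral, the receptor of the nausea-related hormone GDF15, had a ratio of 7.21 (3.55 to 14.1, 15 plate cells). Its 15 plate cells held 3 Dbh counts. Cluster 22, led by Grp, Th and Cartpt, had a ratio of 4.54 (2.39 to 8.21, 16 plate cells). Cluster 13 had a ratio of 0.0999, with 1 plate cell against 125 droplet cells. The ratios of clusters 11 (0.463), 12 (0.599) and 15 (1.40) had intervals that included 1. Among Slc32a1-rich clusters, cluster 18, led by Ebf3 and Ndnf, stood highest with a ratio of 7.197 (4.58 to 11.2, 34 plate cells), followed by cluster 24 with 3.01 (1.11 to 7.03, 7 plate cells) and clusters 10, 3 and 1 with 2.31, 1.85 and 1.82. Cluster 2, led by Defa24, Syndig1l and Zic1, was at 0.329. Cluster 8 of the same group was led by Fos, Fosb and Hspa1a, genes of recent activity and stress, and its ratio of 0.675 (0.286 to 1.37) included 1. The Slc17a6-rich clusters 4, 5, 6 and 7 had ratios of 0.129, 0.0650, 0.209 and 0.247. Cluster 23 of that group, led by Ebf3 and Eya1, went the other way with 3.01 (1.11 to 7.03, 7 plate cells), and the intervals of its other 4 clusters included 1. No plate neuron fell into the Chat-rich clusters 9 and 21, which held 187 droplet neurons (6.32%) and were led by Prph and Nppb and by Vip and Nts. A count of 0 among 237 plate neurons allows a share of up to 1.27%. The unresolved cluster 20 held 53 droplet neurons and no plate neuron. The orders of clusters 3, 10 and 24 depended on the assignment method.

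**Figure D1:**
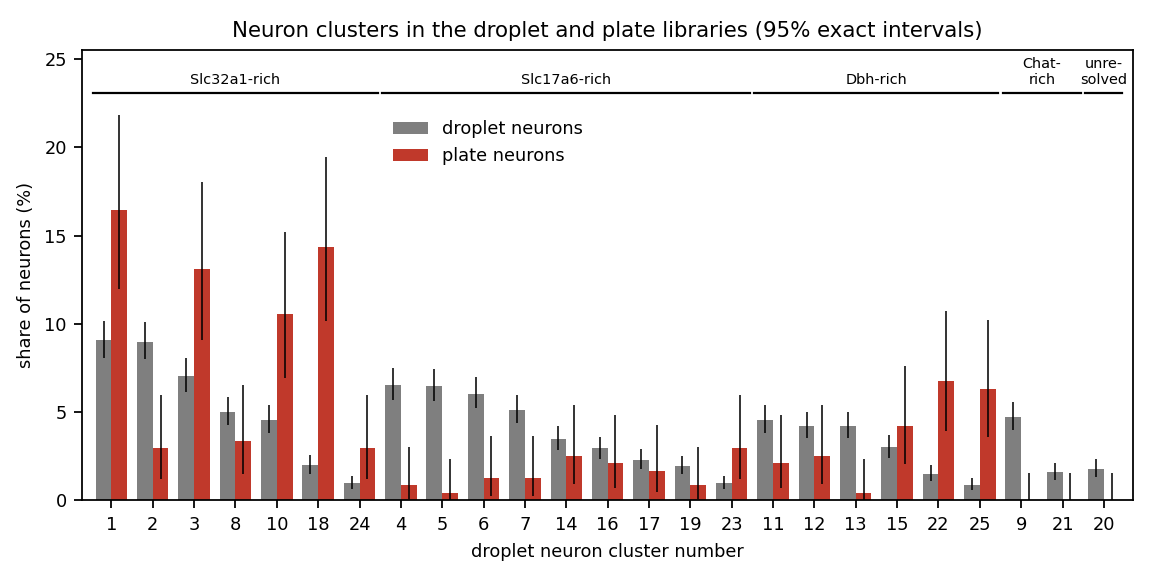
Share of neurons (percent) in each of the 25 droplet neuron clusters, by cluster number, for droplet neurons (grey) and plate neurons (red), with exact 95% intervals as lines and cluster groups named above the bars. Plate bars stand above droplet bars in clusters 1, 3, 10, 18 and 24, in clusters 15, 22 and 25 and in cluster 23, and no plate neuron lies in clusters 9, 20 and 21.

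Transmitter genes were then read cell by cell, with every neuron thinned to 2000 counts, which left out 17 droplet and 3 plate neurons. Slc17a6 (ENSMUSG00000030500, chromosome 7, 51622006 to 51671119, plus strand) was found in 17.5% of plate and 34.7% of droplet neurons. Gad1 (ENSMUSG00000070880, chromosome 2, 70553072 to 70602014, plus strand), which makes GABA, was found in 34.6% and 24.8%. Slc6a5, the glycine transporter of inhibitory endings, was found in 10.7% and 4.69%. Gad2 was found in 37.2% and 39.5%, and Slc32a1 in 11.97% and 17.7%. Chat, which makes acetylcholine, was found in 0.427% of plate and 2.34% of droplet neurons. Tph2, which makes serotonin, was found in no plate neuron and in 0.306% of droplet neurons. Without thinning, Slc17a6 was found in 31.6% of plate neurons (median 5117 counts) and 57.9% of droplet neurons (median 18084 UMIs). As background, thinned droplet astrocytes (median 5366 UMIs before thinning) had Slc17a6 in 2.18% and Gad1 in 3.02% of cells. In thinned oligodendrocytes (median 6463.5 UMIs) these were 4.35% and 1.45%.

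Of the adrenergic genes, Th (ENSMUSG00000000214, chromosome 7, 142892752 to 142931128, minus strand), the first enzyme of catecholamine synthesis, was found in 9.40% of plate and 3.57% of droplet neurons after thinning. Without thinning the shares were 13.5% and 12.8%. Dbh (ENSMUSG00000000889, chromosome 2, 27165233 to 27183200, plus strand) was found in 6.84% of plate and 7.78% of droplet neurons, against 0.671% of astrocytes and 1.45% of oligodendrocytes. Pnmt, which makes adrenaline, was found in 2.99% and 0.714%, and Slc6a2, the noradrenaline transporter, in 1.71% and 1.19%. In the droplet library Ddc was found in 16.3% of neurons, 18.8% of oligodendrocytes and 2.35% of astrocytes, and Maoa in 13.9% of neurons, 11.6% of oligodendrocytes and 20.5% of astrocytes. Among peptides, Cartpt was found in 29.1% of plate and 22.6% of droplet neurons, and Gal in 4.27% and 36.3%. Gal was also found in 16.6% of astrocytes and 20.3% of oligodendrocytes of the droplet library, and Npy in more astrocytes (9.56%) than droplet neurons (2.82%).

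Gene levels summed over all neurons differed with the same order for most transmitter genes. Deep cells weigh more in such sums, and the Chat-rich clusters 9 and 21, with medians of 70207.5 and 85741 UMIs, held no plate neuron. The list medians and percentiles below are of sums without weighting to the plate cluster makeup. Slc17a6 was lower in plate than in droplet neurons, at 150 against 287 CPM, a fold of 0.522 (0.446 to 0.607). Th was higher, at 160 against 27.8 CPM, a fold of 5.74 (4.90 to 6.69), while Dbh had a fold of 0.822 whose interval included 1 (0.637 to 1.04). Gad1 had a fold of 1.47 (1.31 to 1.65) and Slc6a5 one of 3.25 (2.56 to 4.09), while Gad2 and Slc32a1 were at 0.844 and 0.640. Chat had a fold of 0.105 (0.0215 to 0.307) on 3 plate counts, and Tph2, with 1 plate count, one of 0.781 (0.0195 to 4.499). Of the other adrenergic genes, Phox2a (0.139) and Slc18a2 (0.214) were lower. Pnmt was neither higher nor lower by the rule, with a fold of 4.11 (2.43 to 6.55) on 19 plate counts, as were Ddc (1.47), Gch1 (1.27), Slc6a2 (0.907) and Maoa (0.765). With droplet neurons weighted to the plate cluster makeup, the log2 fold of Th was 1.65 and that of Slc17a6 was -0.71, while Gad1 turned to -0.58. Slc32a1 and Gad2 then stood lower, at -1.86 and -1.43, and Chat (-0.03) and Slc18a2 (-0.24) were within 2-fold.

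Among 24 neuropeptide genes, 5 were higher, 8 lower and 11 neither. Pnoc (5.61), Npy (3.98), Cartpt (2.59), Cck (2.48) and Penk (2.03) were the higher ones. Gal (0.0301), Vip (0.0442) and Adcyap1 (0.0997) were among the lower ones. Gcg, the precursor of GLP-1, had no plate count and was also lower, and Prlh, with no plate count either, was at least 15.6-fold lower. The list's median log2 fold was -0.48, at percentile 0.27 of random lists. Of 16 receptors for appetite and visceral signals, Gfral (ENSMUSG00000059383, chromosome 9, 76164102 to 76213657, minus strand) was higher, with a fold of 5.88 (4.87 to 7.04). Glp1r (at least 3.76-fold lower), Oxtr (0.182), Cckar (0.232) and Npy2r (0.419) were lower, and 11 were neither (median 0.07, percentile 15.2). Weighted to the plate makeup, Gfral turned to a log2 fold of -0.27 and Cckar to 1.37, and Cck (0.22), Penk (0.74), Vip (-0.26) and Oxtr (-0.55) were within 2-fold. So were Cck (0.89), Penk (0.85), Oxtr (-0.86) and Cckar (-0.83) with the mean over cells of CPM, and Penk (0.71) with median-ratio scaling. Penk was also within 2-fold with a total without ribosomal protein genes and Malat1 (0.958).

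Of the genes of immune signalling, 2 were higher and 1 was lower by the rule between the neurons of the libraries, and many had too few counts to be measured. Of 20 cytokine receptor genes Il13ra1 was higher (3.07, 2.20 to 4.19), none was lower and 19 were neither (median 0.18 over 16 measured genes, percentile 15.6). Of 13 genes of LPS and prostaglandin sensing, none was higher or lower (median 1.03 over 8 measured genes, percentile 73.1). Of 16 inflammatory genes, Nfkbia, an inhibitor of NF-kB that NF-kB itself induces, was higher (2.92, 2.12 to 3.93) and 15 were neither or not measured (median 1.55 over 5 measured genes, percentile 62.2). Of 13 interferon response genes, Bst2 was at least 2.08-fold lower and 12 were neither (median 0.76 over 10 measured genes, percentile 49.7). These counts do not show that the genes left as neither were alike.

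Of 16 immediate early genes, which follow neuronal activity, 2 were higher, 6 lower and 8 neither. Npas4 (12.98, 9.66 to 17.2) and Dusp1 (3.31) were higher. Fos (0.434, 0.348 to 0.536), Homer1 (0.275), Fosl2 (0.123) and Nr4a2 (0.0274) were lower. Egr3, with no plate count, is counted with them, though it is shown only to be at least 1.40-fold lower. The list's median of -0.49 lay at percentile 0.39. Of 9 genes of dissociation stress, Hspa1a was higher (2.25), Hsp90aa1 (0.358) and Hspb1 (0.282) were lower and 6 were neither (median -0.43, percentile 5.01). Of 12 Hox genes of the caudal hindbrain, Hoxc5 was higher (2.65), 5 were lower, among them Hoxd4 (0.294), Hoxb3 (0.373), Hoxa4 (0.413), Hoxc4 (0.453) and Hoxb4 (0.493), and 6 were neither (median -0.44, percentile 1.91). With the same weighting the log2 fold of Nr4a2 moved from -5.19 to -2.36. Fosl2 (-2.31) and Homer1 (-1.76) stayed lower, and Npas4 (3.79) and Dusp1 (2.08) stayed higher. Hspb1 turned to 0.36, and Fos (-0.93) and Hoxc4 (-0.97) were within 2-fold. So were Hspb1 (-0.18) with the mean over cells of CPM, Hspa1a (0.86) with median-ratio scaling and Fos (-0.98) with neurons from marker lists. Hoxb4 was within 2-fold with all genes in the total (-0.98) and with the total without 4 genes of ribosomal or repeated sequence (-0.98).

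Receptor and channel lists held few members beyond 2-fold. Of 11 ionotropic glutamate receptor genes, Grin2a (2.36) and Grin2b (2.01) were higher, Grik1 (0.467) was lower and 8 were neither (median -0.01, percentile 41.9). Among GABA-A and glycine receptor genes, Glra1 was higher (4.69), and the list's median was -0.00152 (percentile 47.5). Of 10 acetylcholine receptor genes, Chrm3 was higher (2.96), Chrna5 lower (0.225) and 8 neither (median -0.35, percentile 4.20). Of 8 adrenergic receptor genes, Adra2a was lower (0.319) and 7 were neither (median 0.01, percentile 14.1). Of 15 voltage-gated channel genes, Kcnq3 (0.264) and Kcnd2 (0.373) were lower and 13 neither (median -0.39, percentile 2.92). Of 11 synaptic vesicle genes, Syn1 (0.402) and Syp (0.422) were lower and 9 neither (median -0.31, percentile 11.6). Weighted, Chrna5 turned to 0.26, and Grin2a (0.91), Grik1 (-0.70) and Adra2a (-0.98) were within 2-fold. With median-ratio scaling Grin2a (0.93) and Grin2b (0.70) were too, as they were with the mean over cells of CPM (0.91 and 0.94). With neurons from marker lists Grik1 was at -0.72 and Grin2b at 0.995. Grin2b was also within 2-fold with a total without ribosomal protein genes and Malat1 (0.947). Over all 15033 genes with at least 10 counts and a count in both libraries the median log2 fold was 0.22, and median-ratio scaling set it at -0.09.

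Over all genes between the neurons, Cd86 led with a fold of 1459 (482 to 7223), followed by Ptp4a1 (346), Rtl8c (190), Hsd17b11 (119), Zbed5 (117), Tonsl (113), Ick (86.8), Sh3bp1 (54.0), Coro1b (52.0) and Fstl3 (51.3). The fold of Ptp4a1 is that of ENSMUSG00000026064, with 21 droplet counts. The droplet library also lists ENSMUSG00000117310 under that name, which overlaps it on the same strand and is not in that fold. At the other end stood Prph, a filament gene of motor and peripheral neurons, with a fold of 0.00200 (5.06e-05 to 0.0111). Atp6v0c (0.00288), Rnasek (0.00487), Kcnk9 (0.00701), Rab4b (0.0111), Ube2v1 (0.0134), Clic1 (0.0137), Slc39a7 (0.0219), Tomm6 (0.0253) and Gng10 (0.0262) followed. Atp6v0c, a subunit of the vesicular proton pump, had counts in 99.4% of droplet and 3.38% of plate neurons. In cells of the other named classes, 17 of these 20 genes had a fold in the same direction with an interval excluding 1.

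**Figure D2:**
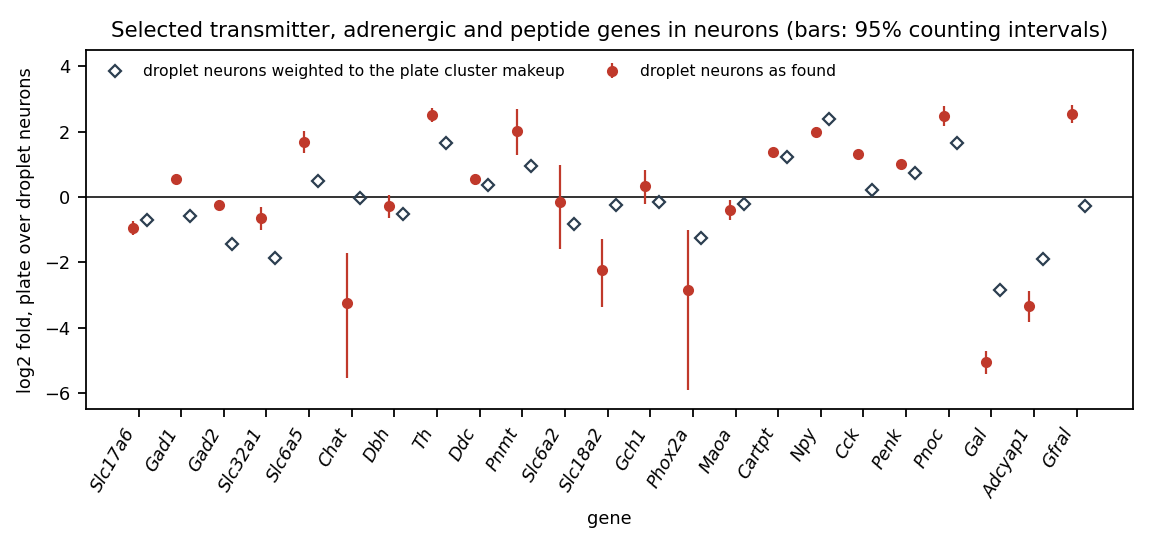
Log2 fold of plate over droplet neurons for selected transmitter, adrenergic, peptide and receptor genes, with droplet neurons as found (red points, lines for 95% counting intervals) and weighted to the plate cluster makeup (open diamonds). Th lies above 0 both ways (2.52 and 1.65), and Gfral moves from 2.55 to -0.27.

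What marks the neurons of the nucleus that express Dbh was asked in the droplet library with a gate on Dbh alone. Dbh-positive cells made up 15.9% of droplet neurons (14.6% to 17.3%, 472 of 2960). Against the other 2488 neurons they had higher levels of genes for making and clearing noradrenaline. Besides the gate gene, Slc6a2 (fold 31.9, 23.0 to 45.1), Th (10.5, 9.43 to 11.6), Ddc (7.30), Gch1 (5.93), Maoa (3.78) and Phox2a (2.46) were higher by at least 2-fold. Pnmt (1.97) and Slc18a2 (1.86) were not. The list thus had 7 higher members with Dbh counted and none lower, and its median log2 fold without the gate gene was 1.92 (percentile 100 of random lists). With cluster 11, the cluster with the highest share of Dbh-positive cells, in place of the gate, the median of the whole list was 0.27. That cluster held 26.7% of the Dbh-positive cells, and the rest stood among the neurons it was compared with. Th UMIs were found in 49.2% of Dbh-positive and 5.91% of other neurons, and those of Slc18a2 in 24.4% and 10.9%. The Dbh-positive cells had more UMIs (median 25052 against 17372).

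Dbh-positive neurons mostly carried Slc17a6 and had lower levels of inhibitory genes than the other neurons. Slc17a6 was found in 95.1% of them and 50.8% of the others, with a fold of 2.46 (2.39 to 2.54). Slc32a1 (0.0432), Gad1 (0.0394), Slc6a5 (0.140), Gad2 (0.186) and Chat (0.382) were lower, and Tph2 was higher (5.91) on 41 counts against 29. Of 24 neuropeptide genes, 7 were higher, 10 lower and 7 neither (median 0.09, percentile 96.8). Prlh (532) was the highest, though found in only 2.75% of Dbh-positive cells, before Npy (10.3), Nmb (4.03), Tac2 (4.01) and Grp (3.34). Cartpt was at 2.37 and found in 86.4% of Dbh-positive cells. Gcg (0.0107), Crh (0.0219), Sst (0.0562), Calca (0.0911) and Pnoc (0.139) were the lowest.

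Of 16 appetite and visceral receptor genes, Casr (45.5), Gfral (12.7, 11.1 to 14.5), Calcr (12.2), Glp1r (7.44) and Npy1r (2.75) were higher in Dbh-positive neurons. Cckar (0.205), Oprm1 (0.260), Npy2r (0.261), Ghsr (0.436) and Gipr (0.458) were among 6 lower ones, and 5 were neither (median 0.03, percentile 60.5). Of 20 cytokine receptor genes, Tgfbr2 was higher (2.95, 1.80 to 4.77), Il17ra (0.144), Tnfrsf1b (0.334) and Lifr (0.374) were lower and 16 were neither (median -0.09, percentile 23.7). None of 13 LPS and prostaglandin sensing genes (median 0.55 over 8 measured genes, percentile 96.4) or 16 inflammatory genes (median 0.09 over 6 measured genes, percentile 55.2) was higher or lower by the rule. Of 13 interferon response genes, Ifit1 (6.74) and Irf7 (3.11) were higher, 4 were counted as lower and 7 were neither (median -0.15, percentile 21.4). The lower ones were Ifi27l2a (0.370), Ifit2 (0.439), and Isg15 and Rsad2, which had no Dbh-positive count. The exact conditional intervals of the folds of Isg15 and Rsad2 reached 0.547 and 0.847.

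The other lists held at most 3 members each beyond 2-fold. Egr3 (0.112), Ier2 (0.299) and Nr4a2 (0.470) were lower among 16 immediate early genes and 13 were neither (median -0.03, percentile 43.3). None of 9 dissociation stress genes (median 0.03, percentile 68.2), 12 Hox genes (median -0.10, percentile 6), 13 GABA-A and glycine receptor genes (median -0.31, percentile 0) or 11 synaptic vesicle genes (median -0.27, percentile 0) was higher or lower. Adrb1 (0.217) and Adra1a (0.469) were lower among 8 adrenergic receptor genes (median -0.61, percentile 0.53), and Chrm2 (0.134) and Chrm3 (0.281) among 10 acetylcholine receptor genes (median -0.26, percentile 3.90). Of 11 ionotropic glutamate receptor genes, Grin2c was higher (3.00), Grin2a (0.397) and Grik2 (0.442) were lower and 8 were neither (median -0.23, percentile 0.38). Of 15 voltage-gated channel genes, Kcna1 was lower (0.358) and 14 were neither (median -0.28, percentile 0.0350).

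Over all genes the largest folds of Dbh-positive neurons were those of Rd3 (96.2), Npff (52.5, 50.6 to 54.6), Olfr574 (47.0), Insm2 (39.9) and Gc (35.0), before Slc6a2, Ndufa4l2 (31.5), Fbp2 (27.8), Clec1a (24.3) and Gast (20.2). Npff (ENSMUSG00000023052, chromosome 15, 102523839 to 102524942, minus strand) is the precursor of neuropeptide FF. The smallest were those of Lemd1 (0.00927), Slc30a3 (0.0271), Gad1, Crym (0.0422), Slc32a1, Neurod2 (0.0445), Bcl11b (0.0493), Sst, Arhgap15 (0.0706) and Zic1 (0.0711). In the plate library the same gate took 16 of 237 neurons (6.75%, 3.91% to 10.7%), 15 of them in Dbh-rich clusters. Of these 16, all had Cartpt, 15 had Ddc, 14 had Slc17a6, 12 had Th and none had Slc32a1. The shares of the libraries are not comparable, since plate neurons had fewer counts (median 5117 against 18084). With cluster 11 in place of the gate, Slc18a2, Phox2a, Prlh, Nmb, Grp and Glp1r were lower than in other neurons, and Gch1, Gfral (log2 0.03), Ifit1 (0.86) and Il17ra (-0.59) were within 2-fold. With a gate of at least 1 UMI the genes Chat (-0.48), Ghsr (-0.90), Gipr (-0.83), Lifr (-0.78), Tnfrsf1b (-0.58), Ifit2 (-0.43), Ier2 (-0.84), Nr4a2 (-0.33), Adra1a (-0.89) and Grik2 (-0.91) were within 2-fold, as was Gipr (-0.88) with at least 3.

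Which cells of the nucleus carry the genes that sense inflammation was read from CPM by class in the droplet library. Receptors and sensors stood highest most often in microglia, border macrophages and endothelial cells. Of 20 cytokine receptor genes, 16 had at least 20 counts in their highest class. Microglia were highest for 5 of them, among them Tgfbr1 (476 CPM, 435 to 519), Ifngr1 (423) and Il6ra (131). Border macrophages were highest for 4, among them Il10rb (294) and Lifr (282), and endothelial cells for 4, among them Tgfbr2 (246), Osmr (116) and Il1r1 (48.3, 33.0 to 68.1). Il6st, the shared subunit of the IL-6 receptor family, was highest in astrocytes (376), Il1rap in oligodendrocytes (194) and Tnfrsf1a in fibroblasts (149). The interval lay apart from that of the next class for 7 of the 16. In neurons Il1r1 was at 0.639 CPM (0.457 to 0.871), Il6ra at 0.176 and Osmr at 0.0320, while Ifngr2 was at 37.7, above endothelial cells (22.6), Il6st at 27.0, Lifr at 26.3 and Ifnar2 at 22.5.

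Of 13 genes of LPS and prostaglandin sensing, 5 were named and 4 had intervals apart. Cd14, the LPS coreceptor (ENSMUSG00000051439, chromosome 18, 36725067 to 36726798, minus strand), was highest in border macrophages (338 CPM, 270 to 418), as was Ly96 (119). Lbp, which binds LPS, was highest in fibroblasts (210), Myd88 in microglia (22.3) and Ptger1 in oligodendrocyte precursors (19.6). Cd14 had no count in 2960 neurons, which allows up to 0.0480 CPM. Tlr4, the LPS receptor, had 38 counts in microglia (35.4 CPM), 11 in border macrophages (43.8 CPM) and 1 in neurons. The prostaglandin receptors Ptger3 and Ptger4 were at 1.28 and 7.39 CPM in neurons.

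Of 16 inflammatory genes, 6 were named and 5 had intervals apart. Nfkbia (989 CPM, 915 to 1068), Icam1 (134) and Socs3 (95.0) were highest in endothelial cells, and Tgfb1 (145), Ccl4 (42.8) and Il1a (33.5) in microglia. Of 13 interferon response genes, 12 were named and 7 had intervals apart. Endothelial cells were highest for 6, among them Isg15 (205), Ifit1 (107) and Rsad2 (55.8), and border macrophages for Bst2 (656) and Ifi27l2a (585). B2m was highest in microglia (1976), Ifit3 in fibroblasts (87.4), Gbp2 in ependymal cells (46.8) and Ifit2 in oligodendrocyte precursors (42.2). Of 8 adrenergic receptor genes 4 were named and none had intervals apart. Adra2a (43.9), Adra1a (15.4) and Adra1b (10.1) were highest in neurons, and Adrb1 (17.9) in ependymal cells. The highest class stayed the same for 34 to 40 of the 43 named genes under 4 alternatives. Another class was highest for Adra1a, Adra1b and Tgfb1 under 3 of the 4, and for Adra2a, Gbp3 and Ptger1 under 2. Counts in the small classes were few, with 51 border macrophages, 65 fibroblasts and 37 pericytes and smooth muscle cells.

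**Figure D3:**
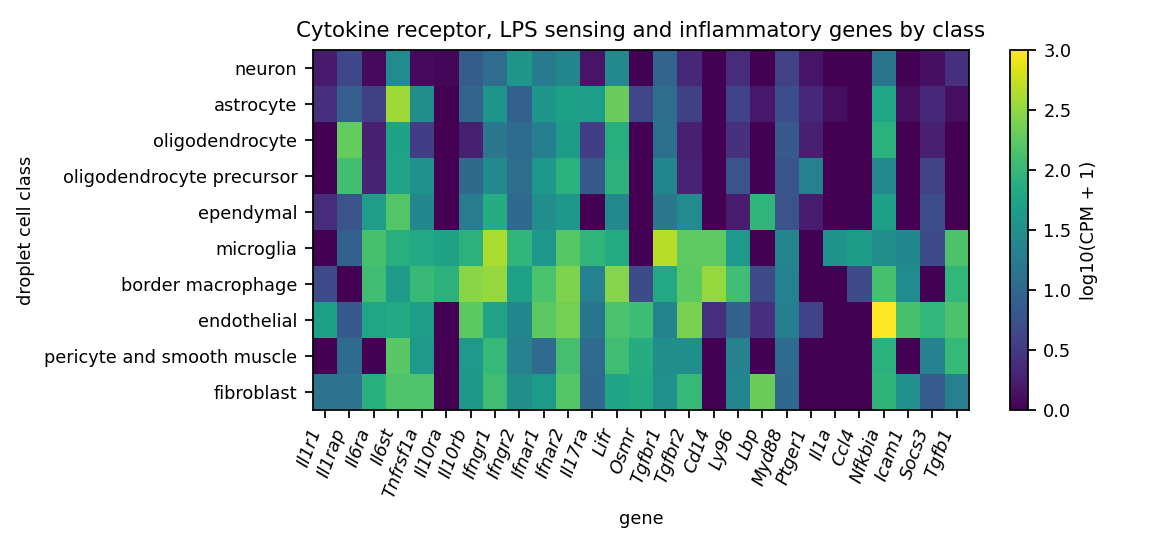
Level of cytokine receptor, LPS sensing and inflammatory genes (columns) in droplet cell classes (lines of the map), as log10 of CPM plus 1 in colour. Microglia, border macrophages and endothelial cells hold most of the bright fields, such as Nfkbia in endothelial cells (989 CPM) and Cd14 in border macrophages (338 CPM).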

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

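The tests of the Slc32a1-rich clusters and of Th, and the look at marker features below, were chosen only after the results were seen, while both tests of the largest and smallest folds were set before.

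The plate table also lists features that are not mouse genes and that the comparisons do not use. The feature listed as WRPE had 587 counts, in 205 of 384 deposited plate cells (53.4%, 48.3% to 58.5%). It is given here as a signal in data outside the comparisons, picked because it had counts, where a count of 0 would allow a share of up to 0.781%. TDTOMATO, CRERECOMB, EYFP and MCHERRY had no count in any of the 384 cells. WRPE was found in 63.7% of 237 plate neurons (328 CPM), in 55.7% of 61 cells of other named classes (1075 CPM) and in 39.5% of 38 cells in unnamed clusters. Among neurons it was found in 75.5% of Dbh-rich (61.7% to 86.2%), 63.6% of Slc17a6-rich (45.1% to 79.6%) and 59.6% of Slc32a1-rich ones (51.3% to 67.5%). These intervals overlap, and the cells were not thinned. Among other classes it was found in 16 of 26 astrocytes, 8 of 11 ependymal cells and 1 of 7 microglia. After thinning, WRPE was found in 41.0% of 234 neurons and 60.9% of 23 cells of other named classes. As background, the Ai9 allele carries an element called WPRE behind tdTomato; whether the feature stands for it was not tested, and no gate was read from it.

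The largest and smallest folds between plate and droplet neurons belonged to 20 genes, 10 each way. Different neuron clusters in the libraries were argued against as the whole cause, since after weighting 0 of the 20 genes had an absolute log2 fold under 1, though Prph moved from -8.97 to -3.41 and Clic1 from -6.19 to -2.18. That the tables count these genes differently whatever the cell remains a candidate explanation, since 17 of the 20 had a fold in the same direction in the other named classes. The exceptions were Prph and Kcnk9, with no plate count in those classes and intervals that included 1, and Clic1 (0.894, 0.510 to 1.46). The step that would make the counts differ was not tested, and the LPS label and the mouse line stay open as untested.

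More plate than droplet neurons lay in Slc32a1-rich clusters (63.7% against 37.6%). That the assignment at plate depth moved neurons there was argued against as the whole cause by a count made cell by cell: 53.4% (46.8% to 59.9%) of thinned plate neurons had inhibitory genes without Slc17a6, against 38.8% (37.0% to 40.6%) of droplet neurons. Slc17a6 alone was found in 15.4% and 29.4%, both in 2.14% and 5.30%, and neither in 29.1% and 26.5%. Loss of neurons with much RNA in the plate library cannot be told apart, since Spearman's rho between a cluster's median UMIs and its plate to droplet ratio was -0.18 (-0.60 to 0.28) over 23 clusters, and the Chat-rich clusters left out of it, with the highest medians (70207.5 and 85741 UMIs), held no plate neuron. A difference between the tables in counting Slc17a6 or the inhibitory genes (after weighting, Slc32a1 was at log2 -1.86 and Gad2 at -1.43), the sort, the mouse line and the LPS label stay open as untested.

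Th was higher in plate neurons (log2 fold 2.52) without a like difference of Dbh (fold 0.822). Within clusters 22 and 25 Dbh was lower in plate cells, with a fold of 0.431 (0.282 to 0.635). It was at 0.632 (0.400 to 0.953) in cluster 22. In cluster 25 it was at 0.164 (0.0333 to 0.490), on 3 counts in 15 plate cells. Within the other Dbh-rich clusters it was at 0.888 (0.630 to 1.22). More neurons of some Dbh-rich clusters in the plate library were argued against as the whole cause, since after weighting the log2 fold of Th was still 1.65 (1.41 to 1.89), though that interval reached below the 1.5 set as the bound. Whether the tables count Th differently whatever the cluster cannot be told apart. Within Dbh-rich clusters other than 22 and 25 the fold of Th was 5.92 (4.52 to 7.63). Folds of single clusters were unequal, from 15.9 (11.2 to 22.1) in cluster 12 to 1.49 (0.951 to 2.26) in cluster 25. Cluster 15 had no Th count in 10 plate cells. Clusters 22 and 11 were at 3.55 and 2.91, on 16 and 5 plate cells, and cluster 13 had 1 plate cell without Th. These intervals leave out the spread between the few plate cells of each cluster. The LPS label and the mouse line stay open as untested.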

How the results depend on the processing

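The centred correlation, the assignment without transmitter, adrenergic and peptide genes, and the total without 4 repeat genes were chosen only after the result was seen; the other 26 alternatives were set before. For 395 results there were 1942 values under alternatives. Outside the main counting interval in the same direction lay 69 of the folds between the libraries, with 5 reversed and 472 inside. Among folds of Dbh-positive neurons these were 87, 7 and 182, and among cluster ratios 14, 3 and 110. Of list medians 8 moved and 167 did not, of shares of cells with a count 260 and 220, of class shares 35 and 90, and of the remaining values 29 and 184. Slc32a1-rich clusters held 57.4% to 66.7% of plate neurons and Dbh-rich ones 20.3% to 22.6% over the assignment alternatives, and 62.4% to 97.9% of plate neurons kept their cluster among those that assigned the same neurons anew. Clusters 9, 20 and 21 have no log2 ratio, since they held no plate neuron. The log2 fold of Dbh stayed between -0.59 and -0.24. Depth limits the shares of cells with a count, which depend on thinning and on the count asked for.

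The neuron share of droplet cells was 46.0% from 500 UMIs up, 59.1% from 2000 UMIs up, 59.98% with at most 10% mitochondrial UMIs, 49.8% at resolution 2 and 62.99% with classes per cell from marker lists. The neuron share of plate cells was 84.2% from 2000 counts up and 76.5% with classes per cell. Slc17a6 was found in 31.6% of plate neurons when not thinned, which leaves more counts per cell, and, with at least 2 counts asked for, which can lower a share by construction, in 3.85%, and Dbh in 2.56%. With median-ratio scaling, which lowers all folds alike, the log2 fold of Slc17a6 was -1.25 and that of Th 2.21. With droplet neurons weighted to the plate cluster makeup these were -0.71 and 1.65, and Gad1 (-0.58), Gfral (-0.27), Cckar (1.37), Hspb1 (0.36) and Chrna5 (0.26) reversed, as the clusters that carry them count for more or less.

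Cluster ratios reversed with the centred correlation for neuron cluster 3 (log2 -0.48) and neuron cluster 10 (-1.85), and with the 15 nearest droplet neurons for neuron cluster 24 (-1.22); the cause was not tested. Dbh-positive neurons made up 20.6% of droplet neurons with at least 1 UMI and 14.1% with at least 3, and 3.80% of plate neurons with at least 3, by construction of the gate. With cluster 11, the cluster with the highest share, in place of the gate these shares were 4.56% and 2.11%. The log2 fold of Slc17a6 in Dbh-positive neurons was 1.11 with at least 1 UMI and 1.82 in cluster 11. Cluster 11 also reversed Slc18a2 (-4.57), Gch1 (-0.0024), Phox2a (-5.35), Prlh (-7.06), Nmb (-2.22), Grp (-2.37) and Glp1r (-0.36). It held 26.7% of the Dbh-positive cells, and the rest stood among the neurons it was compared with. Slc18a2 was found in 3.70% of its cells and 47.2% of cluster 12, and Glp1r in 8.89% and 58.4% of cluster 15. This alternative thus describes 1 Dbh-rich cluster and not Dbh-positive neurons as a set. No further cause was tested.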

Other observations

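The values below, of single Dbh-rich clusters, were chosen for reporting only after the data were seen, and no explanation was tested for them.

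In the 6 Dbh-rich clusters of the droplet library the following genes were found. The shares are of cells as found, at median UMIs from 14807 (cluster 15) to 29374 (cluster 13), and were not compared at equal depth. As background, droplet astrocytes (median 5366 UMIs) had Slc17a8 in 0.955%, Th in 0.637%, Calcr in 0.159%, Glp1r in 0.478%, Slc6a2 in 0.478%, Pnmt in 0.159%, Gfral in 0.637%, Slc18a2 in 2.23% and Cartpt in 12.6% of cells. Cluster 11 had Slc17a8, the vesicular glutamate transporter VGLUT3, in 91.1% of 135 cells and Th in 81.5%, and was led by Npff. Cluster 12 had Calcr, the calcitonin receptor, in 31.2% of 125 cells, Glp1r in 24% and Slc18a2 in 47.2%. Cluster 13 had Cartpt in 97.6% of 125 cells and Slc17a8 in 50.4%, but Th in 4%. Cluster 15 was led by Glp1r, the receptor of GLP-1, which 58.4% of its 89 cells had, and had Slc6a2 in 49.4% and Gfral in 20.2%. Cluster 22 had Pnmt, which makes adrenaline, in 38.6% of 44 cells, with Th in 93.2% and Gfral in 22.7%. Cluster 25 had Gfral in all 26 cells, Th in 80.8%, Glp1r in 38.5% and Slc17a8 in 42.3%.

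Between the libraries, the summed level of Cartpt had unequal folds within these clusters. The intervals cover counting error only and leave out the spread between the few plate cells of each cluster. It was higher in plate cells of cluster 12 (fold 6.66, 5.79 to 7.64, 6 plate cells), cluster 15 (5.79, 3.99 to 8.21, 10 cells), cluster 11 (4.37, 3.62 to 5.23, 5 cells) and cluster 22 (1.74, 1.60 to 1.89, 16 cells). It was lower in cluster 25 (0.153, 0.0182 to 0.569, 15 cells) on 2 plate counts. Slc17a6 was lower in plate cells of the same 5 clusters, with folds from 0.235 in cluster 15 to 0.609 in cluster 11. Ddc was at 1.10 (0.886 to 1.36) over the Dbh-rich clusters other than 22 and 25, and at 1.41 (1.20 to 1.65) over clusters 22 and 25. Cluster 13 had 1 plate cell and is left out of the values for single clusters.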
